A study of Mus musculus with 4 samples.

How the data were processed

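RNA sequencing of bone marrow neutrophils from wild-type mice gave 4 libraries, 2 from cells given DMSO and 2 from cells given Aβ40 at 20 µg/ml for 4 h. The dose and time are from the series' design text, and the groups from the labels. Per the labels' protocols, total RNA was extracted on Qiagen columns and libraries were made with an Illumina kit. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse build mm10, without their order or role. The strandedness and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes may not have been told apart.

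The authors deposited a table of raw read counts per gene and a table of FPKM (fragments per gene length and library depth), each with 54532 genes and with gene symbols, types and positions. The deposited counts are whole numbers and were used as they are. The deposited FPKM equal the counts divided by gene length and by an effective library size that follows the median-ratio scaling of DESeq2, as checked on the values, so they carry a composition correction as well as depth. Of the gene identifiers, 54409 were found in GENCODE M21 and 53842 of those had the same symbol. That annotation and its genome served only to give GC content.

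Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups, which left 13479, and library sizes were scaled by TMM. The comparison of Aβ40 against DMSO used the quasi-likelihood test (glmQLFit and glmQLFTest, intercept and group, 2-sided) with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. There were 2 residual degrees of freedom, to which the fit added 6.88 prior ones by sharing variance over genes, and the common biological coefficient of variation was 0.210. Log2 fold changes are Aβ40 minus DMSO, with standard errors from the same fit. CPM are TMM-scaled, and means and SD are over the 2 libraries of a group. Groups did not overlap for 45.1% of tested genes, where chance gives 33.3% with 2 libraries against 2. On simulated counts for these 13479 genes, with 100 genes at each fold in each of 5 simulations, the test recovered 40.2% of 2-fold and 78.2% of 4-fold changes, or 56.1% and 98.6% above 5 CPM, with a mean of 11.6 false calls.

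There were 37 gene lists, fixed before the data were examined, as were the alternatives not named as added. They cover cytokines and chemokines, NF-kB targets and regulators, interferon-stimulated genes, cytosolic DNA sensing and STING, NET formation, primary granules, secondary and tertiary granules, immature and mature neutrophils, neutrophil surface receptors, amyloid receptors and clearance, the inflammasome, apoptosis, immediate early genes, the unfolded protein and heat shock responses, NRF2, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, lysosome and autophagy, glucocorticoid response, cell cycle, NADPH oxidase, lipid mediators, ribosomal proteins, mitochondrially encoded genes, and 10 other cell types of marrow (monocytes, dendritic cells, B cells, T and NK cells, erythroid cells, eosinophils, basophils and mast cells, megakaryocytes, progenitors, endothelium and stroma). Of 895 list symbols, 1 was not used because no symbol matched it. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with a correlation estimated per list, and with fry, each with Benjamini-Hochberg adjustment over the 37 lists. On simulated counts camera found a list of 20 genes shifted by 1 on the log2 scale in 5 of 5 simulations and called 3 of 100 unshifted lists at an unadjusted p under 0.05. The simulated genes were drawn independently and the unshifted lists at random, so these rates do not cover lists of correlated genes.

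The rule for named genes took the 12 called genes with the largest rise and the 12 with the largest fall among protein-coding genes with a mean of at least 5 CPM and non-overlapping groups, leaving out predicted genes and immunoglobulin and T cell receptor segments. It added, per list, up to 4 called members in the main direction and 2 in the other, or the 2 most abundant members where none was called, and 13 genes fixed by name (Padi4, Mpo, Elane, Cybb, Il1b, Tnf, Cxcl2, Nfkbia, Tmem173, Tlr2, Tlr4, Cd36 and App). There were 14 eligible rising genes and 0 falling ones, so the rule named 83 genes in all. Members that passed only over their list alone, and Prg2, Epx, Ear1, Ear2, Ighm, Igkc, Jchain, Cd74, Cd300a, Rag1, Pax5, Eomes, Cd8b1, Nkg7, Ctsg, Prkcd, Cyba, Il6, Il1a, Ighd, Iglc3, Gm10154, Ltb4r1, Csf3r, Slc11a1, Mmp25, Pik3cd, Oas3, Cd4 and Thy1, were named after their values were seen.

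Alternatives were median-ratio, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, no filter or a mean count of at least 10, protein-coding genes only, the replicate number as a block, leaving out each library, and limma on log2(FPKM + 1) or log2(FPKM + 0.1). A crossed block and the removal of GC and length trends (mgcv 1.9.3) were added after the data were seen. With 2 libraries a group, other splits of the samples were not counted.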

Results

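Gene expression was measured by RNA sequencing in neutrophils taken from the bone marrow of wild-type mice. The cells had been exposed either to DMSO, a common solvent, or to amyloid-beta 40 (Aβ40), a peptide cut from the amyloid precursor protein, at 20 µg/ml for 4 h. Each group held 2 libraries, named here DMSO 1 and 2 and Aβ40 1 and 2. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Per the series' description, the experiment addressed how Aβ40 leads neutrophils to release extracellular traps (NETs), webs of chromatin coated with granule proteins.

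Total counts per library were 19524125 in DMSO 1, 17212264 in DMSO 2, 17684621 in Aβ40 1 and 19163503 in Aβ40 2. Between 13183 and 13521 genes had at least 10 counts in a library, and 1 count corresponded to between 0.0523 and 0.0585 CPM, counts scaled to library size. Transcripts of S100a8 and S100a9, the most abundant calcium-binding proteins of neutrophils, took 7.07% ± 1.20 (SD, n = 2) of all counts with DMSO and 8.54% ± 0.350 (SD, n = 2) with Aβ40. Over genes, the Spearman correlation was 0.978 within the DMSO pair and 0.987 within the Aβ40 pair. DMSO 1 correlated more closely with Aβ40 2 (0.982) than with DMSO 2. The chi-square statistic per degree of freedom was 51.4 for the DMSO pair and 15.6 for the Aβ40 pair, so neither pair was one library deposited again.

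Genes of B lymphocytes, eosinophils and T or natural killer (NK) cells were higher with Aβ40, while the lists of neutrophil granule and NET formation genes held members on either side of 0 and gave no call. Camera called the first 3 lists higher at a preset correlation, but not with an estimated one (Benjamini-Hochberg adjusted p = 0.195 each). In the eosinophil list and in the T and NK cell list 1 member each was called over all genes. Of 13479 genes tested, 17 rose and 0 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Their folds ran from 2.67 for Ccr7, a chemokine receptor of lymphocytes and dendritic cells, to 4.86 for Iglc3, an immunoglobulin light-chain constant region. In all 17, both Aβ40 libraries lay above both DMSO libraries. The others were Fcrla, Cd79b, Cd79a, Ear6, H2-Ob, Ighd, Vpreb3, Gm10154, Mzb1, Slamf6, Vpreb1, Scd1, Gimap6, Gzmb and Ms4a1.

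Fcrla, an Fc receptor-like protein of B cells (ENSMUSG00000038421, mm10 chromosome 1, 170917576 to 170927583), had the smallest p-value. It rose from 14.6 ± 0.461 CPM to 57.6 ± 4.24 CPM (SD, n = 2 each), a log2 fold change of 1.98 (SE 0.19; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0282). Cd79a (ENSMUSG00000003379, chromosome 7, 24897381 to 24902197) and Cd79b (ENSMUSG00000040592, chromosome 11, 106311341 to 106314762) encode the signalling chains of the B cell receptor. Cd79a rose from 18.4 ± 0.604 to 60.2 ± 4.42 CPM and Cd79b from 43.7 ± 3.05 to 135 ± 5.68 CPM (SD, n = 2 each). Ms4a1, the gene of the B cell antigen CD20 (ENSMUSG00000024673, chromosome 19, 11249675 to 11266241), rose by a log2 fold change of 1.88 (SE 0.26). Vpreb1, a part of the surrogate light chain of precursor B cells, and Vpreb3, a related protein of the B lineage, rose by log2 fold changes of 2.03 (SE 0.26) and 2.01 (SE 0.24). Ear6, a ribonuclease of eosinophils (ENSMUSG00000062148, chromosome 14, 51853699 to 51854643), rose from 183 ± 12.4 to 568 ± 65.8 CPM (SD, n = 2 each), a log2 fold change of 1.63 (SE 0.19). Gzmb, a cytotoxic protease of T and NK cells, rose by 1.54 (SE 0.22) on the log2 scale, and Scd1, a fatty acid desaturase, by 1.96 (SE 0.26). Reads of Ear6, Iglc3 and Vpreb1 can be split with near-identical relatives, and Gm10154 is a processed pseudogene, so these levels are uncertain.

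Of the 17 genes, 9 belonged to the fixed lists of cell types other than neutrophils, against 0.178 if calls were spread evenly over the tested genes (2-sided Fisher's exact test, p = 2.62e-14, with 141 tested genes in those lists). The test takes genes as independent, though 6 of the 9 were B cell markers, which may move together. Its p-value does not measure the spread between libraries. In the list of B cell markers all 20 tested members had a positive log2 fold change, with a median of 1.60. Among them 6 rose with adjustment over all genes and 19 rose when adjusted over the list alone. Rag1, part of the recombinase of precursor lymphocytes, was at 2.12 (SE 0.31) and Pax5, a B-lineage transcription factor, at 1.54 (SE 0.23). The member not called in either way was Jchain, the joining chain of secreted antibodies, at 0.20 (SE 0.26). Ighm, with the highest level of the list, was at 439 ± 62.0 CPM with DMSO and 748 ± 9.71 CPM with Aβ40 (SD, n = 2 each).

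Of 11 eosinophil markers, 1 rose with adjustment over all genes and 10 rose when adjusted over the list alone, with a list median of 1.19. Prg2, the major basic protein of eosinophil granules, was at 850 ± 104 CPM with DMSO and 2044 ± 131 CPM with Aβ40 (SD, n = 2 each), and Epx, eosinophil peroxidase, was at 0.76 (SE 0.17) on the log2 scale. Ear1 and Ear2, close relatives of Ear6, were at 1.33 (SE 0.21) and 1.19 (SE 0.20). The exception was Cd300a, at -0.17 (SE 0.17). Among 19 T and NK cell markers all had a positive log2 fold change, with a median of 0.97. Gzmb rose with adjustment over all genes and 11 members rose when adjusted over the list alone, among them Cd8b1 at 1.75 (SE 0.41) and Eomes at 2.32 (SE 0.61). Both were scarce, at means of 4.05 and 2.19 CPM. Members that did not pass included Nkg7, with a mean of 42.3 CPM, at 0.18 (SE 0.19), and Thy1 at 0.22 (SE 0.49).

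Marker lists of other cells of the marrow had lower medians, though single members such as C1qb at 1.62 (SE 0.32) and Mrc1 at 1.56 (SE 0.34) were high. Of these lists, only the erythroid and platelet markers were tested against another list, that of B cells. The dendritic cell list had a median of 0.38, with 1 member, Ccr7, called over all genes and 5 higher when adjusted over the list alone, namely Ccr7, H2-Aa, H2-Eb1, Ly6d and Ccr9. Ccr7 is also a gene of lymphocytes, and whether this list rose apart from the B cell list was not tested. The monocyte and macrophage list had a median of 0.29, with 0 called over all genes and 3 higher when adjusted over the list alone, C1qb, C1qc and Mrc1. Camera, a test of a list against all other genes with a preset correlation of 0.01, called these 5 lists higher, with Benjamini-Hochberg adjusted p = 2.86e-48 for B cells, 3.96e-20 for eosinophils, 5.97e-12 for T and NK cells, 3.51e-06 for dendritic cells and 0.00248 for monocytes. None of the 5 calls held with a correlation estimated from the data: adjusted p = 0.195 with an estimated correlation for each of the B cell, eosinophil and T and NK cell lists, 0.299 for dendritic cells and 0.498 for monocytes. In simulations of independent genes, a list of 20 genes shifted by 1 on the log2 scale reached an unadjusted p no lower than 0.00373 in this setting of camera. A lone list at such a p would not pass the adjustment over 37 lists, so these losses do not decide whether the lists moved. Erythroid markers had a median of -0.04, megakaryocyte and platelet markers of -0.24, basophil and mast cell markers of 0.34, progenitor markers of 0.09 and endothelial and stromal markers of 0.43, with 0 members called over all genes and none of these 5 lists called by camera. The erythroid list differed in sign between its median and its mean of 0.06. Adjusted over the list alone, Cpa3, Fcer1a, Cd200r3 and Il4 were higher and Il6ra lower among basophil and mast cell markers, Ctla2a was higher among progenitor markers, and Pecam1 and Sparc were higher among endothelial and stromal markers. Sparc, at a mean of 0.382 CPM, was too low for a fold to be given.

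**Figure D1:**
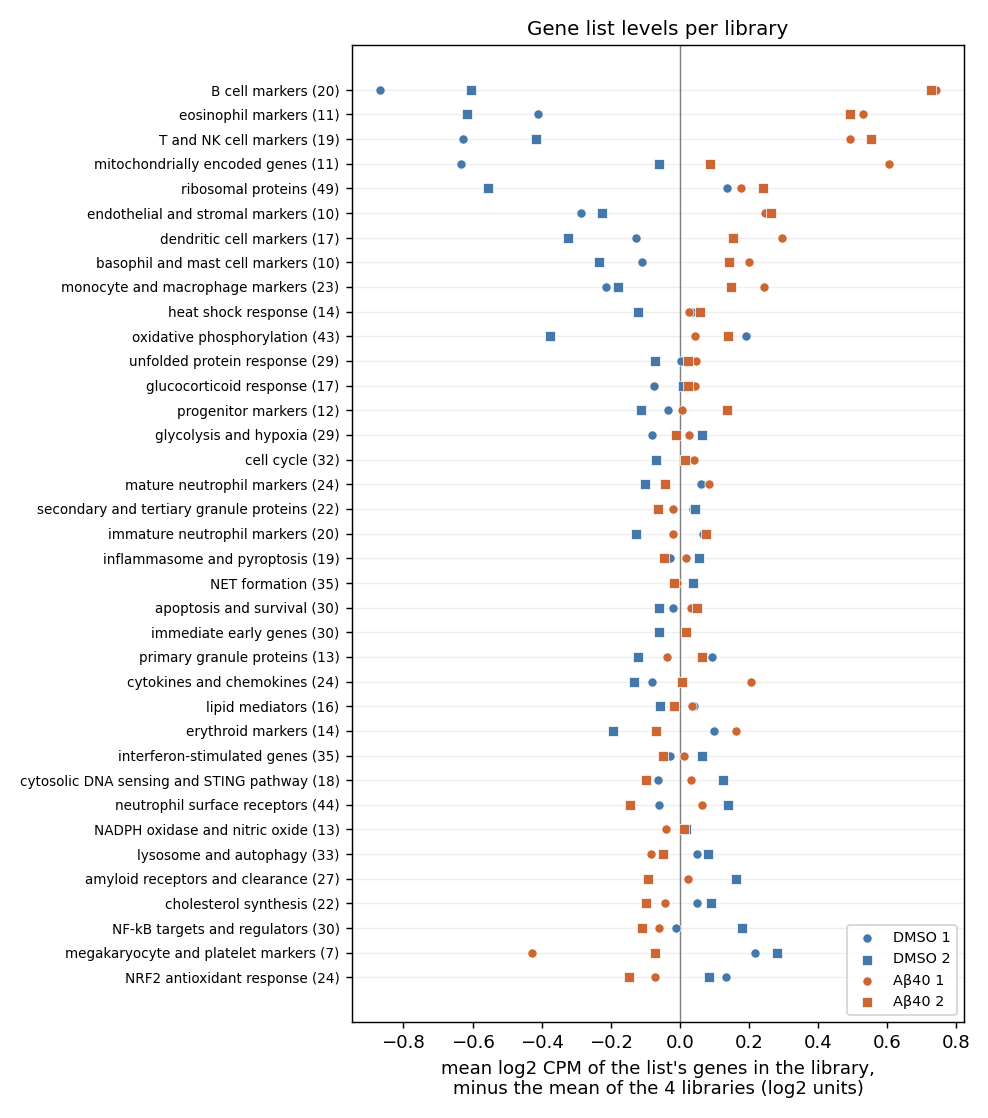
Mean log2 CPM of each gene list in each library, minus the mean of the 4 libraries, in log2 units, for 37 lists with the number of tested members in brackets; blue marks DMSO and orange Aβ40, circles replicate 1 and squares replicate 2. The B cell list sits at -0.87 and -0.60 in the DMSO libraries and at 0.74 and 0.73 in the Aβ40 libraries, while the ribosomal protein list is low in DMSO 2 alone (-0.56).

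The NET formation list, made of the chromatin-modifying enzyme Padi4 and of granule, oxidase and signalling genes, held 35 tested members, of which 0 were called over all genes and 0 when adjusted over the list alone. Its median was 0.01 and its mean -0.04, which differ in sign (camera, Benjamini-Hochberg adjusted p = 0.539). Padi4 (ENSMUSG00000025330, chromosome 4, 140745865 to 140774236), the histone-citrullinating enzyme, was at 260 ± 100 CPM with DMSO and 191 ± 12.4 CPM with Aβ40 (SD, n = 2 each), a log2 fold change of -0.45 with a 95% confidence interval from -1.02 to 0.13. The DMSO spread came from DMSO 2, with 331 CPM, against 189 CPM in DMSO 1. Mpo, the myeloperoxidase of primary granules, was at -0.30 (SE 0.19), Elane, neutrophil elastase, at -0.03 (SE 0.19), and Cybb, the catalytic subunit of the NADPH oxidase, at -0.16 (SE 0.18). Lcn2 and Ltf, granule proteins with the highest levels in the list, were at 0.12 (SE 0.21) and 0.07 (SE 0.22). The widest departures in the list were Prkcd at -0.63 (SE 0.21), Cyba at -0.62 (SE 0.23) and Pik3cd at -0.55 (SE 0.17), all signalling or oxidase genes, and Ctsg, cathepsin G, at 0.59 (SE 0.18), none of which passed the adjustment.

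**Figure D2:**
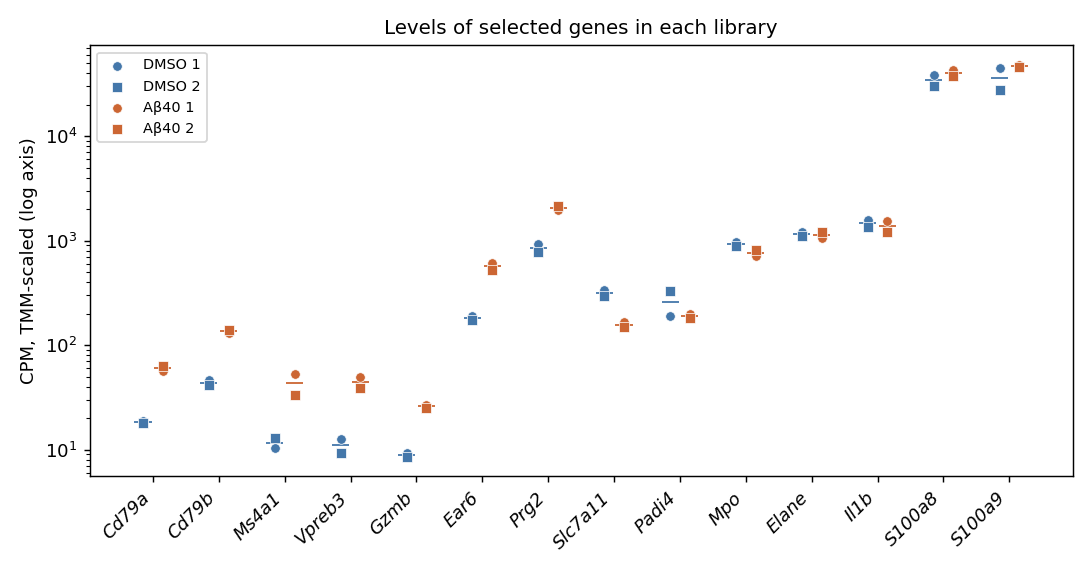
TMM-scaled CPM of 14 genes in each library, on a log axis; blue marks DMSO and orange Aβ40, circles replicate 1 and squares replicate 2, and lines the group means. The DMSO and Aβ40 libraries separate for Cd79a, Cd79b, Ms4a1, Vpreb3, Gzmb and Ear6, and, without a call over all genes, for Prg2, Slc7a11, Mpo and S100a9. Their means lie close together for Elane (1152 and 1127 CPM) and Il1b (1458 and 1385 CPM).

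The neutrophil lists showed no called member over all genes or over the list alone in the edgeR quasi-likelihood test. Median log2 fold changes were -0.004 for primary granule proteins, 0.04 for secondary and tertiary granule proteins, 0.03 for immature neutrophil markers, 0.07 for mature neutrophil markers, -0.09 for neutrophil surface receptors and -0.09 for the NADPH oxidase and nitric oxide genes, none called by camera. The medians of both granule lists differed in sign from their means, of 0.02 and -0.09. S100a8 was at 0.23 (SE 0.25) and S100a9 at 0.38 (SE 0.29), and Ngp, a secondary granule protein, at 0.18 (SE 0.25). Members well below 0 included Ltb4r1, a leukotriene receptor, at -0.76 (SE 0.19), Csf3r, the receptor of granulocyte colony-stimulating factor, at -0.61 (SE 0.20), the metal transporter gene Slc11a1 at -0.60 (SE 0.19), and the metalloprotease genes Mmp9 at -0.55 (SE 0.18) and Mmp25 at -0.51 (SE 0.16). Members well above 0 included Ctsg at 0.59 (SE 0.18) and Lyz2 at 0.51 (SE 0.23), and the highest member of the surface receptor list was at 0.65. DESeq2 called Ltb4r1 lower (Benjamini-Hochberg adjusted p = 0.0242), where the edgeR quasi-likelihood test gave an adjusted p of 0.244.

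The lists of NF-kB targets, NRF2 antioxidant genes and lysosome and autophagy genes were lower with Aβ40 by camera at the preset correlation, but none was called with an estimated one. In the NRF2 list 3 of 24 members fell when adjusted over the list alone and 0 over all genes, and the median was -0.31 (camera, Benjamini-Hochberg adjusted p = 0.00136; adjusted p = 0.413 with an estimated correlation). The median was -0.18 without DMSO 1 and ran to -0.38 without Aβ40 2. Slc7a11, the cystine transporter, was at 317 ± 30.0 CPM with DMSO and 157 ± 10.8 CPM with Aβ40 (SD, n = 2 each), a log2 fold change of -1.01 (SE 0.18). Gclm, a subunit of the enzyme that starts glutathione synthesis, and Srxn1, sulfiredoxin, fell by 0.66 and 0.70 on the log2 scale. The ferritin genes Fth1 and Ftl1, the most abundant of the list, were at -0.86 (SE 0.28) and -0.60 (SE 0.20). In the lysosome and autophagy list 3 of 33 members fell when adjusted over the list alone, the progranulin gene Grn, the autophagy kinase gene Ulk1 and the transcription factor gene Tfe3, and 0 over all genes. Its median was -0.10 (camera, Benjamini-Hochberg adjusted p = 0.0314; adjusted p = 0.498 with an estimated correlation), and camera did not call it without DMSO 2, Aβ40 1 or Aβ40 2 (medians -0.06, -0.15 and -0.04; adjusted p = 0.0622, 0.0665 and 0.0629). Without DMSO 1 the median was -0.19. In the NF-kB list 24 of 30 members had a negative log2 fold change, with a median of -0.20 and 0 called in either way (camera, Benjamini-Hochberg adjusted p = 0.00487; adjusted p = 0.578 with an estimated correlation). Camera did not call it without DMSO 2 (median -0.19) or without Aβ40 2 (median -0.24). With trends of GC content and gene length removed it was not called either (median -0.19, camera, Benjamini-Hochberg adjusted p = 0.0559). The median thus stayed about as far from 0. The mean score of the list, however, was 0.18 in DMSO 2 and -0.01 in DMSO 1, against -0.06 in Aβ40 1 and -0.11 in Aβ40 2. Nfkbia, the inhibitor that NF-kB itself induces, was at -0.003 (SE 0.19), with 409 ± 59.6 and 408 ± 27.2 CPM (SD, n = 2 each).

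Inflammatory messengers and sensors gave no call over all genes in the edgeR quasi-likelihood test. DESeq2 called Oas3, an interferon-stimulated gene, lower (Benjamini-Hochberg adjusted p = 0.00538), where the edgeR quasi-likelihood test gave an adjusted p of 0.190. From the lists below, DESeq2 also called Alox15 and Rgs1 higher. The cytokine and chemokine list had a median of -0.01 and a mean of 0.21, which differ in sign, with Il1b at -0.07 (SE 0.21), Tnf at -0.23 (SE 0.19), Cxcl2 at -0.12 (SE 0.18) and Cxcl10 at -0.02 (SE 0.19). Il6 was at 0.86 (SE 0.24) and Il1a at 1.42 (SE 0.50) without passing either adjustment. Medians were -0.04 for interferon-stimulated genes and -0.06 for the cytosolic DNA sensing and STING pathway, in which Tmem173, the gene of STING, was at 0.78 (SE 0.21). Amyloid receptors and clearance genes had a median of -0.12, with Tlr2 at -0.16 (SE 0.18), Tlr4 at 0.26 (SE 0.28), Cd36 at -0.12 (SE 0.27) and App at -0.35 (SE 0.19). The inflammasome and pyroptosis list (median 0.03, mean -0.03) and the lipid mediator list (median -0.02, mean 0.01) also differed in sign. In the latter, Alox15, which the eosinophil list also holds, was higher when adjusted over the list alone, at 1.38 (SE 0.24). Among immediate early genes (median 0.01, camera direction down) Rgs1 was the single member higher when adjusted over the list alone, at 1.10 (SE 0.19). Medians were 0.01 for apoptosis and survival, 0.11 for the unfolded protein response, 0.26 for the heat shock response and 0.09 for the glucocorticoid response. None of the lists in this paragraph was called by camera, whose adjusted p-values ran from 0.308 for the amyloid list to 0.940 for the apoptosis, glucocorticoid and lipid mediator lists.

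Ribosomal protein genes and mitochondrially encoded genes were also higher by camera. Of 49 ribosomal protein genes 44 had a positive log2 fold change, with a median of 0.44 (camera, Benjamini-Hochberg adjusted p = 5.89e-09; adjusted p = 0.736 with an estimated correlation). Without DMSO 2, which stood below the other 3 libraries, the median was 0.10 and camera did not call the list (adjusted p = 0.513), and without DMSO 1 the median was 0.81. All 11 mitochondrially encoded genes had a positive log2 fold change, with a median of 0.70 (camera, Benjamini-Hochberg adjusted p = 1.17e-05; adjusted p = 0.578 with an estimated correlation), and mitochondrial genes took 0.986% ± 0.233 of counts with DMSO and 1.46% ± 0.353 with Aβ40 (SD, n = 2 each). The mitochondrial list was lowest in DMSO 1 and highest in Aβ40 1, and its median was 0.35 without Aβ40 1. With trends of GC content and gene length removed the median was 0.36 and camera did not call the list (adjusted p = 0.131). Rpl15 and mt-Co3 were the members higher when adjusted over their list alone, at 0.90 (SE 0.18) and 0.82 (SE 0.22). The remaining lists were not called, with medians of 0.25 for nuclear oxidative phosphorylation genes (15 of 43 members below 0), 0.08 for glycolysis and hypoxia (mean -0.01, which differs in sign), -0.16 for cholesterol synthesis and 0.08 for the cell cycle.

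The absence of calls among falling genes stands beside 771 falling and 877 rising genes with an unadjusted p under 0.05 in the edgeR quasi-likelihood test (674 in all by chance), and beside 36 falling and 94 rising genes called by DESeq2. The count of 17 depended strongly on which library was left out. It became 3 with trends of GC content and gene length removed, where the median log2 fold change of the 17 genes was 1.64 (median SE 0.21), against 1.80 (median SE 0.22) before.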

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

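The tests named here as added, the crossed block and the removal of GC and length trends, were chosen after the results were seen. All 17 called genes were also called under DESeq2, limma-voom, the likelihood ratio test, no filter, median-ratio or library-size scaling, a mean count of at least 10 and both blocks, and 15 of 17 under upper-quartile scaling. The count of called genes became 130 with DESeq2 (94 rising, 36 falling), 221 with the likelihood ratio test (160 and 61), 255 with no filter (185 and 70), and 0 in the 3 limma analyses of FPKM, where 1420, 1408 and 1875 genes had an unadjusted p under 0.05 (smallest adjusted p from 0.142 to 0.493). With the added removal of GC and length trends it was 3. The median log2 fold change of the 17 genes went from 1.80 (median SE 0.22) to 1.64 (median SE 0.21), and their largest adjusted p from 0.0468 to 0.0759, with 14 of them no longer called. The size of change among genes changed, as the number with an absolute log2 fold change over 1, was 17, then 84, 152, 151, 0 and 3 under these settings in the same order. Where no other reason is given, the cause was not tested.

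Leaving out 1 library gave from 0 to 1276 called genes and, as size of change among genes changed, from 0 to 404. The lone library of a group is then assumed to vary like the other group. Without an Aβ40 library the spread came from the DMSO pair alone (0 called), and without a DMSO library from the closer Aβ40 pair (1024 or 1276). The range for Hbb-bs, at -0.04 with all libraries, was from -0.59 to 0.82, and for Hba-a1, at -0.03, from -0.49 to 0.61. Both globin genes were called higher without DMSO replicate 1, and Hbb-bs was called lower without DMSO replicate 2.

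The replicate number as a block gave 27 called genes, all rising and with a large change. The deviations of same-numbered libraries had only a weak negative correlation over genes (-0.187), and 2 pairs with no label for a shared origin do not establish pairing. An added crossed block gave 721 called genes (445 rising, 276 falling), 227 of them with a large change.

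The 10 lists called by camera became 0 with an estimated correlation (smallest adjusted p = 0.195, with 4 lists at an unadjusted p under 0.05) and 0 with fry (smallest adjusted p = 0.0516), though fry's test of change in either direction called 8. In simulations of independent genes a list shifted by 1 reached an unadjusted p from 0.00373 to 0.0188 with an estimated correlation. A lone list at such a p would not pass the adjustment over 37 lists, so the loss of calls in this setting does not decide whether lists moved. Under the other settings from 7 to 14 lists were called. For single lists, 409 of 440 comparisons outside the leave-one-out runs kept their call status, though 7 uncalled ones among them changed sign, 24 lost a call and 7 gained one. For single named genes, 1878 of 2090 kept theirs, of which 43 uncalled ones changed sign, 67 lost a call, 145 gained one and 0 reversed while called.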

Other observations

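Of the tests below, those of cell share and of DMSO 2 were chosen after the results were seen, and those of GC content and gene length before their outcomes were. Values of gene classes that the report does not describe, which were not tested as classes, were as follows. Of 93 immunoglobulin segments 79 had a positive log2 fold change, with a median of 0.76 and 2 called genes, Ighd and Iglc3. Of 568 processed pseudogenes 408 had a positive log2 fold change, with a median of 0.29 and 1 called gene, Gm10154. Among the 36 falling genes that DESeq2 called, and the main test did not, were Sema4a, Slc7a11, Grn, Fth1, Oas3 and Ltb4r1, chosen after their values were seen.

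The mean scores of the B cell, T and NK cell and eosinophil lists were higher in both Aβ40 libraries than in both DMSO libraries, though not each member was (Jchain, Cd4, Nkg7, Thy1 and Cd300a were the exceptions), and the list calls by camera were lost with an estimated correlation (adjusted p = 0.195 each). Other cell types did not all rise alike. Erythroid and platelet markers lay below B cell markers in median log2 fold change (difference -1.69, 2-sided permutation test over genes, p = 1e-05, the smallest it can give). The difference ran from -1.89 to -1.31 without 1 library. The permutation takes genes as independent and does not measure the spread between libraries. These lists were chosen after their medians were seen, so the p-value adds no support. The difference in medians itself goes against a lower share of neutrophils with an equal rise of every other cell type. A lower share with an unequal gain of other cells stays open. Trends of GC content and length are argued against as the whole cause, since the median of the 3 lists was 1.15 after their removal against 1.32 before. The eosinophil median went from 1.19 to 0.85, so a part from these trends stays open there. Of the 17 called genes 14 lost their call, and the median of the 17 was 1.64 against 1.80 at a like SE (median 0.21 and 0.22). Their median fold was thus slightly smaller without a larger SE. A part from these trends therefore stays open for these genes too. The folds of the B cell members were unequal (Cochran's Q per degree of freedom 3.74, p = 6.27e-08, n = 20 genes taken as independent). This does not decide whether a single B-lineage population was gained at one share. Other cells already holding Jchain (218 CPM with DMSO) or Ighm (439 CPM) would hide part of such a gain. More B, T and NK cells and eosinophils among the harvested cells, set by the preparation or the treatment, and a response of these cells to Aβ40 stay open and cannot be told apart, since the 98% of the 50 list members (49) above 0 restate the pattern, and Igkc at 0.31 and Cd74 at 0.40, abundant genes outside the B cell list and chosen after their values were seen, were below most of its members.

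The ribosomal protein and mitochondrially encoded lists were higher with Aβ40 by camera at the preset correlation, but not with an estimated one (adjusted p = 0.736 and 0.578), with 0 members called over all genes by the edgeR quasi-likelihood test (14 and 5 at an unadjusted p under 0.05, and 2 and 0 called by DESeq2), and the lists part on which library carries this. DMSO 2 standing apart may explain the ribosomal list, whose median fell from 0.44 to 0.104 without it, while trends of GC and length left it at 0.344 (Benjamini-Hochberg adjusted p = 2.26e-08 by camera at the preset correlation). For the mitochondrial list DMSO 2 is argued against, as the median was 0.971 without it, but the rise rests on DMSO 1 and Aβ40 1 (scores -0.63 and 0.61, against -0.06 in DMSO 2 and 0.09 in Aβ40 2), with a median of 0.35 without Aβ40 1 and 0.48 without DMSO 1. GC and length trends cannot be told apart from a change in the mitochondrial genes, since their removal took the median from 0.70 (SD 0.268 over 11 genes) to 0.362 (SD 0.289) and the adjusted p to 0.131, with a smaller fold at a like spread.

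The NRF2, NF-kB and lysosome lists were lower with Aβ40 by camera at the preset correlation, but not with an estimated one (adjusted p = 0.413, 0.578 and 0.498) or by fry, with 0 members called over all genes by the edgeR quasi-likelihood test (8, 7 and 5 at an unadjusted p under 0.05, and 2, 0 and 1 called by DESeq2). Of the 7 NF-kB members, 6 were lower and 1 was higher. Over their members the median log2 fold change was -0.169, against -0.170 without DMSO 2 and -0.187 with GC and length trends removed, so neither is the whole cause for the 3 lists together. The NF-kB call ended with the trends removed, where the median went from -0.20 (SD 0.256) to -0.19 (SD 0.237) and the adjusted p to 0.0559, for which the cause was not tested. Without DMSO 2 the NF-kB call ended at a like median (-0.19), and the lysosome call at a smaller one (-0.06 against -0.10). The mean NF-kB score was 0.18 in DMSO 2, against -0.01 in DMSO 1, -0.06 in Aβ40 1 and -0.11 in Aβ40 2. A large part of the shift in the NF-kB mean therefore rests on DMSO 2. A response to Aβ40 may remain as an explanation, untested here, as does a difference in the mix of cells.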
